A study of Mus musculus with 11 samples.

How the data were processed

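Hippocampal tissue was collected with a 0.2 mm punch from coronal slices of frozen brains of female mice, 5 given AC-T and 6 given saline. Polyadenylated RNA was made into stranded libraries and sequenced on an Illumina NextSeq instrument. The submitters' notes name Dragen 4.3.6 for base call conversion, FastQC 0.11.9 for read quality, Salmon 1.9.0 for quantification and the mouse genome build GRCm39. Salmon assigns reads to transcripts by probability, so a read shared between similar genes is divided among them. The labels also mention an upload to a pathway analysis portal. They do not say which step wrote the table, which annotation release was used, or how genes were selected. The values in the table deposited by the authors are expected counts: between 13.7% and 14.7% of the values per library have a fraction, and the library totals differ. They were rounded to whole numbers. Gene positions are not given, because the annotation at hand belongs to an older genome build than the one named in the notes.

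The table held 17118 genes. Of these, 14255 had a value above 0 in all 11 libraries, 35 were at 0 in all, and 2828 were at 0 in some libraries only. In 1543 of the 2828 (54.6%) the lowest value above 0 was at least 20 counts, with a median of 23 counts over all 2828. Across 2786 of them the lowest listed CPM (read count scaled to a common library size) rose with the median length of the annotated transcripts (Spearman rho 0.84 across genes, which are not independent replicates) and with the longest (0.90). Its median was 0.633 CPM per kilobase of the former and 0.530 of the latter, which was added after seeing the data. A listed 0 was therefore read as a value under a limit and not as a count of 0, and no fold change is given for a gene listed at 0 throughout a group. In all, 9.64% of the values in the table were 0.

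Library totals ran from 23.4 to 32.1 M counts (M, mega). Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 2-sided, trimmed mean of M values normalisation, filterByExpr with a minimum count of 10). Benjamini-Hochberg adjusted p values under 0.05 passed. The filter kept 15353 genes, and the biological coefficient of variation was 0.174. CPM values are normalised read counts, with SD over mice. Log2 fold changes are AC-T minus saline, with the SE of the fit. On data simulated from the fitted means and dispersions, 85% of 100 genes changed 1.5-fold and 91% of 100 genes changed 2-fold were recovered, and 3.30% of the calls were false. Simulated genes were drawn independently, without series or tissue differences between libraries, and the changed ones had an average log2 CPM above 1. The simulated shares therefore need not hold for the real libraries.

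The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The 53 lists cover cell types, hippocampal subfields, neighbouring regions and stress, synaptic and metabolic functions. They held 986 genes, of which 935 were matched in the table and 900 were tested. Each list was tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over the 53 lists. It was tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. The score of a list is the mean log2 CPM of its members per library, compared by an exact permutation test over 462 splits of the libraries, whose smallest p is 0.00216. Library measures were compared by the same exact test. Genes named are the 10 largest changes in each direction past the threshold with an average log2 CPM of at least 1 and a symbol that is not a predicted-model name. Up to 4 members with the smallest p are named from each list past its test, and up to 2 from other lists described. A further 10 genes were named whatever their values; 1 of them, Mki67, was not analysed here. Not every gene the rule takes is reported here.

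The first digit of the mouse number divides each treatment into a pair of series (2 and 3 for saline, 5 and 6 for AC-T). The labels do not say what it stands for. No series holds both treatments, so treatment could not be tested within a series. The series were compared within each treatment in a model with 4 group means, and treatment was also fitted with series as a random effect.

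Alternatives were other scaling factors, low-count filters, a robust dispersion, a component of the dissection markers or a surrogate variable (sva 3.50.0) as covariate, omission of each library and of each series, DESeq2 1.42.0, limma-voom, other thresholds, unrounded values, and the other list tests. A fit of genes with a value above 0 in all libraries, and a fit with the thalamic list score as covariate, were chosen after seeing the data. The series states 6 samples per group; 5 AC-T libraries were analysed here.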

Results

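The study concerns the gut, the microbiome and cognition after chemotherapy, and these data hold its measurement of gene expression in the hippocampus. AC-T is a chemotherapy for breast cancer that joins doxorubicin, an anthracycline, and cyclophosphamide, an alkylating agent, with a later course of paclitaxel, which stabilises microtubules. Female C57/BL6 mice aged 12 weeks received 8 weekly intraperitoneal injections. In the AC-T group these were 4 of doxorubicin (2 mg/kg) with cyclophosphamide (50 mg/kg) and then 4 of paclitaxel (5 mg/kg), and in the control group they were 0.9% saline. Samples carry a 1-month label. RNA sequencing of hippocampal punches gave 5 AC-T libraries (mice 501, 502, 503, 600 and 602) and 6 saline libraries (mice 201, 202, 203, 300, 301 and 302).

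Library totals were 30.0 ± 1.42 M counts (M, mega) after AC-T (SD, n = 5) and 28.0 ± 3.29 M after saline (SD, n = 6), with exact permutation p = 0.242. Genes with a value above 0 numbered 15424 ± 213 and 15505 ± 138 (exact permutation p = 0.429), and the 10 most abundant genes took 9.83 ± 1.46% and 11.1 ± 0.907% of the counts (exact permutation p = 0.108). Mitochondrially encoded protein genes took 9.08 ± 1.32% of the counts after AC-T and 10.4 ± 0.847% after saline (exact permutation p = 0.0887). Haemoglobin genes took 0.0216 ± 0.00704% and 0.0392 ± 0.0219% (exact permutation p = 0.113). Xist, the RNA that coats the inactive X chromosome of female cells, was listed at 0 in saline 300 and at 13057 to 22963 counts in the other 10 libraries, although the labels give all mice as female.

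To ask how AC-T altered hippocampal gene expression, the 5 AC-T libraries were compared with the 6 saline libraries. Of 14 thalamic markers 12 were lower after AC-T. Of 11 neocortical markers 4 were higher and 1 lower, and of 13 interneuron markers 4 were higher and 2 lower, while 0 of 53 lists passed with an estimated correlation between genes. Tbr1, a transcription factor of cortical glutamatergic neurons, rose 2.33-fold, from 23.2 ± 4.77 to 54.2 ± 2.15 CPM (SD, n = 6 and 5; adjusted p = 0.000598). Tcf7l2, a Wnt pathway transcription factor expressed in thalamic neurons, fell to 0.377 of its saline level, from 91.4 ± 25.8 to 34.4 ± 9.39 CPM (adjusted p = 0.00550). In total 1301 of 15353 genes passed, 751 higher and 550 lower, with a median absolute log2 fold change of 0.32. Of these, 232 changed at least 1.5-fold and 59 at least 2-fold. A listed 0 in at least 1 library, which the fit takes as a count, occurred in 19 of the 1301 (3 higher and 16 lower). An unadjusted p under 0.05 in edgeR was reached by 3829 of the 15353 genes. Groups did not overlap for 912 of the 1301 genes (70.1%) and for 1155 of all tested genes (7.52%), where chance gives 0.433%.

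The division into higher and lower genes depended on scaling: with upper-quartile factors 593 genes were higher and 663 lower, and with library totals 487 were higher and 548 lower. The count also depended on single libraries. It was 625 without AC-T 502, 681 without AC-T 602, 815 without saline 202 and 832 without saline 300, the library with Xist at 0. With the thalamic list score as covariate, a fit chosen after seeing the data, 1 gene passed in edgeR, Bmp3, and 1370 had an unadjusted p under 0.05. Of 78 named genes past the threshold, 45 lost the call with series as a random effect, 61 with a component of the dissection markers as covariate, and 76 with the thalamic score, where 1 other reversed.

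Among the largest rises, Hs3st2, a heparan sulfate sulfotransferase, was 3.21-fold higher (13.5 ± 1.86 against 4.18 ± 1.502 CPM; adjusted p = 0.00236). Nxph3, a neurexin ligand, rose 2.43-fold, and Cplx3, a complexin of the synaptic vesicle machinery, rose 2.40-fold (log2 1.28 ± 0.24 and 1.26 ± 0.22 SE). Arhgap25, a GTPase activating protein, and Alox12b, an arachidonate lipoxygenase, rose 2.52-fold and 2.35-fold. Myl4, a myosin light chain, rose 4.26-fold with a wide spread between mice (7.46 ± 4.30 against 1.75 ± 0.654 CPM; adjusted p = 0.0135). Trbc2, a constant region of the T cell receptor beta chain, rose 4.52-fold (5.18 ± 2.21 against 1.14 ± 0.249 CPM; adjusted p = 0.00248). Its paralogue has a closely similar sequence, so the share of reads given to Trbc2 is uncertain. Thbs4, a thrombospondin, rose 2.39-fold (adjusted p = 0.0382), but lost its call when any 1 of 7 libraries was left out, with the highest adjusted p, 0.0910, without AC-T 602. Bmp3, a bone morphogenetic protein, was listed at 0 in all 6 saline libraries and at 199, 181, 197, 207 and 193 counts in AC-T 501, 502, 503, 600 and 602. Its fit takes these zeros as counts, so no p is given. Its lowest listed value was 0.922 CPM per kilobase of the longest transcript, against a median of 0.530 and a 95th percentile of 0.850 over genes with some zeros. Per kilobase of the median annotated transcript this value was 0.931, against a median of 0.633 and a 95th percentile of 2.26.

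Among the largest falls were Shox2, a homeobox transcription factor, at 0.399 of the saline level (13.3 ± 4.37 against 33.3 ± 7.28 CPM; adjusted p = 0.00511), and Slitrk6, a transmembrane protein of synapse formation, at 0.389 (adjusted p = 0.00438). Grid2ip, which binds the delta glutamate receptor, fell to 0.374, and Sfrp5, a secreted Wnt inhibitor, to 0.387. Inadl, a scaffold protein of cell junctions, fell to 0.402 (24.9 ± 5.70 against 62.0 ± 15.2 CPM), and Atp2a1, a calcium pump, to 0.410. The unnamed transcript RP23-372N19.2 fell to 0.372 (adjusted p = 0.0121). Baiap3, a regulator of vesicle release, fell to 0.399 (adjusted p = 0.0287), but lost its call when any 1 of 7 libraries was left out, with the highest adjusted p, 0.0791, without AC-T 502. With the thalamic list score as covariate only Bmp3 passed, so these falls and the other rises named above lost the call. Over the alternative fits the log2 fold change nearest 0 was −0.32 for Shox2, −0.47 for Slitrk6 and −0.56 for Grid2ip. It was −0.94 for Sfrp5, −0.36 for Inadl, −0.13 for Atp2a1, −0.41 for RP23-372N19.2 and −0.38 for Baiap3. Zfhx3, a homeobox transcription factor that the naming rule takes, was listed at 0 in all 5 AC-T libraries and in saline 302, and at 475, 471, 540, 356 and 339 counts in saline 201, 202, 203, 300 and 301. Its lowest listed value was 0.674 CPM per kilobase of its longest transcript, and 9.54 per kilobase of the median annotated transcript, which is 1212 bases long against 17152 for the longest. Its fit takes values under a limit as counts of 0, so no p is given for a fall, and the call ended with limma-voom.

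**Figure D1:**
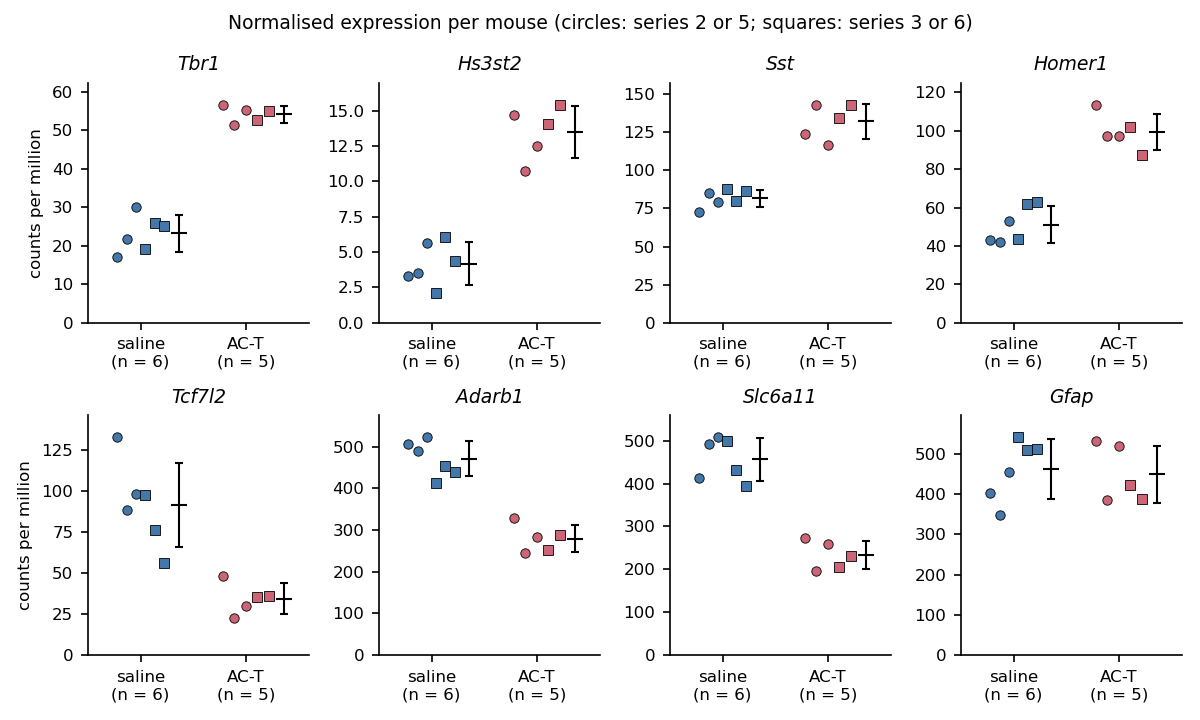
Normalised read counts, CPM (vertical axis, from 0) of 8 genes in each mouse after saline (n = 6) and AC-T (n = 5); circles are mouse series 2 and 5, squares are series 3 and 6, and bars give the mean ± SD. Tbr1 lies at 54.2 ± 2.15 after AC-T and 23.2 ± 4.77 after saline, while Gfap lies at 449 ± 71.0 and 461 ± 74.7.

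The fixed gene lists asked which cell types, regions and functions moved together. Of 53 lists, 12 passed camera, 6 higher and 6 lower. With an estimated correlation 0 of the 53 passed, 3 had an unadjusted p under 0.05, and 3 passed with fry. By the exact permutation test of the list scores 0 of the 53 passed after adjustment (smallest adjusted p = 0.0574). Before adjustment 12 had a p under 0.05. The splits allow no p below 0.00216, so after adjustment over the 53 lists no list could pass alone, however completely its groups separated. The lists with the smallest adjusted p were already at this limit. The adjusted result therefore cannot decide whether a given list changed, here or where adjusted score p values are given below. When the 11 libraries were divided 100 ways into 5 and 6, 75 of the divisions, the real one included, gave at least 12 lists.

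Markers of the thalamus and habenula formed the list with the median log2 fold change furthest from 0. By the difference in list score CA1 markers lay further from 0 (1.38 against −1.12), but by the mean log2 fold change they did not (0.96 against −1.11). The CA1 score was 2.73 in saline 201 and 4.12 to 5.18 in the other saline libraries. Of 14 genes tested, 12 fell and 0 rose, and all 14 fell when adjusted over the list alone (median log2 fold change −1.002; camera adjusted p = 3.41e-26; adjusted p = 0.213 with an estimated correlation; fry adjusted p = 0.00480). Adarb1, an RNA-editing adenosine deaminase, fell from 471 ± 42.2 to 279 ± 33.3 CPM (adjusted p = 0.00125). Amotl1, an angiomotin family protein, fell to 0.534 of saline, Ntng1, the axon guidance protein netrin G1, to 0.520, and Lef1, a Wnt pathway transcription factor, to 0.552. The list score was 4.95 ± 0.336 after AC-T and 6.07 ± 0.359 after saline, and the groups did not overlap. The exact permutation p of the score was 0.00216, the smallest the splits allow, and 0.0574 adjusted over the 53 lists.

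CA1 pyramidal neuron markers were higher as a list. Of 9 genes tested, 1 rose and 0 fell over all genes, and 7 rose when adjusted over the list alone (median log2 fold change 0.93; camera adjusted p = 6.36e-05; adjusted p = 0.905 with an estimated correlation). Mpped1, a metallophosphoesterase, rose 1.90-fold (adjusted p = 0.0255), and this call ended without AC-T 502 (0.0686), AC-T 602 (0.0520), saline 202 (0.0538) or saline 300 (0.0506). Gpr161, an orphan receptor, and Man1a, a mannosidase, had log2 fold changes of 0.89 ± 0.25 and 0.78 ± 0.22 (SE; adjusted p = 0.0527 and 0.0528), and both passed without saline 302 (0.0362 and 0.0250). Nov, a matricellular protein, stood at 1.22 ± 0.43 (adjusted p = 0.101) and passed without saline 201 (0.0347). The CA1 score was 5.67 ± 0.148 after AC-T and 4.29 ± 0.878 after saline (exact permutation p = 0.00649, and 0.0765 adjusted over the 53 lists), in the libraries whose thalamic scores were 4.51 to 5.37 and 5.64 to 6.55. Against saline series 2, 6 CA1 markers rose (median 1.39), against saline series 3, 0 passed in edgeR (median 0.43), and between the saline series 3 were higher in series 3 (median 0.93). With the thalamic score as covariate the CA1 median was −0.13, with a median SE per gene of 0.46.

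Neocortical markers passed with 4 genes higher and 1 lower of 11, and 5 higher and 2 lower adjusted over the list alone (median 0.06; camera adjusted p = 0.0418; adjusted p = 0.917 with an estimated correlation). Besides Tbr1 and Cplx3, Lamp5, a membrane protein of a class of cortical neurons, rose 1.51-fold (adjusted p = 0.00707). Fezf2, a transcription factor of deep-layer neurons chosen after its values were seen, rose and stood at 30.9 ± 3.66 CPM after AC-T and 14.8 ± 5.94 after saline (adjusted p = 0.0225, and 0.0628 without AC-T 502). Rorb, a nuclear receptor of layer 4 neurons, fell to 0.670 (adjusted p = 0.0181, and 0.0501 without AC-T 502). The list call ended without AC-T 501 (0.0539), AC-T 503 (0.103) or saline 302 (0.113), and the median was −0.03 without AC-T 502. The list score had an exact permutation p of 0.119. The neocortical median was 0.21 against saline series 3 and −0.11 against saline series 2, and −0.19 between AC-T series 6 and 5. The thalamic score differed between the same libraries, 4.95 ± 0.336 against 6.07 ± 0.359, and with it as covariate the neocortical median was 0.45, with a median SE of 0.31.

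**Figure D2:**
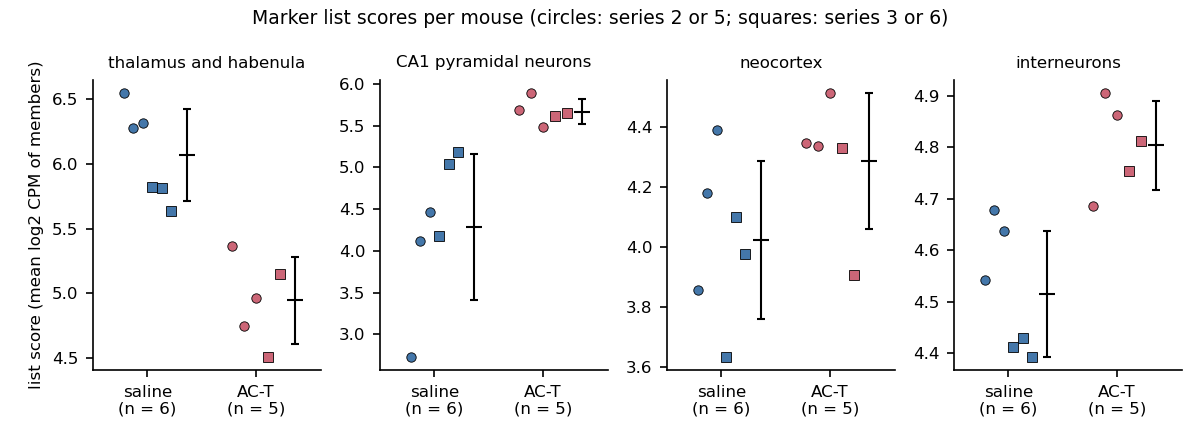
Mean log2 CPM of the members of 4 marker lists (vertical axes, each with its own range) in each mouse after saline (n = 6) and AC-T (n = 5); circles are mouse series 2 and 5, squares are series 3 and 6, and bars give the mean ± SD. Thalamic scores lie at 4.51 to 5.37 after AC-T and at 5.64 to 6.55 after saline.

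Interneuron markers moved both ways. Of 13 genes, 4 rose and 2 fell, and 6 rose and 2 fell adjusted over the list alone (median 0.20; camera adjusted p = 0.000115; adjusted p = 0.213 with an estimated correlation; fry adjusted p = 0.00480). Sst, the neuropeptide somatostatin, rose 1.62-fold (132 ± 11.7 against 81.8 ± 5.61 CPM; adjusted p = 0.000593). Crhbp, which binds corticotropin-releasing hormone, rose 2.12-fold, Lhx6, a transcription factor of somatostatin and parvalbumin neurons, 1.67-fold, and Npy, the neuropeptide Y gene, 1.48-fold. Calb2 and Pvalb, which encode the calcium-binding proteins calretinin and parvalbumin, fell by 1.05 ± 0.28 and 0.65 ± 0.17 on the log2 scale (SE; adjusted p = 0.0378 and 0.0391); they were chosen after their values were seen. The fall of Calb2, which is also in the thalamic list, lost its call on omission of any 1 of 9 libraries (highest 0.0852, without AC-T 602), and that of Pvalb on omission of any 1 of 6 (highest 0.103, without AC-T 502). Interneuron scores were 4.804 ± 0.0864 after AC-T and 4.52 ± 0.122 after saline (exact permutation p = 0.00433, and 0.0765 adjusted over the 53 lists), beside thalamic scores of 4.95 ± 0.336 and 6.07 ± 0.359. With the thalamic score as covariate the median was 0.46, with a median SE of 0.26. Against saline series 3, 6 interneuron genes rose and 0 fell in edgeR, against saline series 2, 4 rose and 2 fell, and 0 differed between the saline series.

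Synaptic genes were higher as lists. Of 28 postsynaptic density genes, 7 rose and 1 fell, with 12 and 1 adjusted over the list alone (median 0.20; camera adjusted p = 6.36e-05; adjusted p = 0.917 with an estimated correlation). Homer1, a scaffold protein of glutamate receptors, rose 1.95-fold (99.5 ± 9.45 against 51.0 ± 9.59 CPM; adjusted p = 0.00192). Nrgn, a calmodulin-binding protein of dendrites, rose 1.36-fold, Cacng3, an auxiliary subunit of AMPA receptors, 1.32-fold, and the scaffold gene Shank3 fell to 0.748. Of 23 presynaptic genes, 6 rose and 0 fell, with 8 and 0 adjusted over the list alone (median 0.16; camera adjusted p = 6.36e-05; adjusted p = 0.917 with an estimated correlation). Stx1a, a syntaxin of vesicle fusion, rose 1.64-fold (adjusted p = 0.00686) and the vesicle protein gene Sv2b 1.54-fold (adjusted p = 0.0138). Against saline series 2, 14 postsynaptic genes rose and 1 fell (median 0.34), and against saline series 3, 2 rose and 2 fell (median 0.11); between the saline series 2 were higher in series 3 (median 0.23). For presynaptic genes the numbers were 3 and 1 against series 2 and 7 and 0 against series 3. List scores had exact permutation p values of 0.0281 and 0.00866, and 0.166 and 0.0765 adjusted over the 53 lists. These lists moved in the libraries with the lower thalamic scores, 4.95 ± 0.336 against 6.07 ± 0.359.

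Of 16 immediate early genes, which neurons induce on activity, 4 rose and 1 fell, with 8 and 2 adjusted over the list alone (median 0.33; camera adjusted p = 0.0254; adjusted p = 0.949 with an estimated correlation). Besides Homer1, Egr1 rose 1.595-fold (135 ± 8.89 against 84.6 ± 21.95 CPM; adjusted p = 0.0186). Arc, a cytoskeletal protein of active synapses, had a log2 fold change of −0.25 ± 0.15 (SE; adjusted p = 0.346). Of the 5 calls, those of Nr4a2, Nr4a3 and Ier2 ended on omission of any 1 of 7, 8 and 9 libraries; Ier2 was chosen after its values were seen. The list call ended without saline 300 (adjusted p = 0.143), and the list score had an exact permutation p of 0.0909, in libraries with thalamic scores of 4.95 ± 0.336 and 6.07 ± 0.359.

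Astrocyte and endothelial lists were lower. Of 14 astrocyte genes, 3 fell and 0 rose, with 5 and 0 adjusted over the list alone (median −0.22; camera adjusted p = 0.000479; adjusted p = 0.925 with an estimated correlation). Slc4a4, a bicarbonate transporter, fell to 0.748 of saline (adjusted p = 0.0121). S100b, a calcium-binding protein, and Aqp4, the water channel of astrocyte endfeet, fell to 0.754 and 0.727 (adjusted p = 0.0356 for each); they lost the call on omission of any 1 of 8 and of 7 libraries, to at most 0.0858 without AC-T 602 and 0.0945 without AC-T 502. Gfap, the intermediate filament gene that marks reactive astrocytes, had a log2 fold change of −0.04 ± 0.13 (SE; adjusted p = 0.895). Of 14 endothelial genes, 1 fell and 0 rose, with 5 and 0 adjusted over the list alone (median −0.17; camera adjusted p = 0.00166; adjusted p = 0.917 with an estimated correlation). Pecam1, an endothelial adhesion molecule, fell to 0.865 (adjusted p = 0.0403) and lost the call on omission of any 1 of 8 libraries, to at most 0.0939 without AC-T 502. Scores of the astrocyte and endothelial lists had exact permutation p values of 0.0693 and 0.0130, and 0.245 and 0.0983 adjusted over the 53 lists. Between AC-T series 6 and 5 the astrocyte median was −0.30, further from 0 than the change after AC-T, and the endothelial median −0.09, with 0 and 1 genes lower past the threshold in edgeR. Thalamic scores in these libraries were 4.95 ± 0.336 and 6.07 ± 0.359.

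Genes of mitochondrial respiration and of the ribosome were lower as lists, with small changes per gene. Over all 15353 genes tested in edgeR, 1301 passed and 3829 had an unadjusted p under 0.05. Beside these shares, the numbers of respiratory and ribosomal genes past the threshold, and at an unadjusted p under 0.05, do not stand out. Of 82 nuclear-encoded oxidative phosphorylation genes, 2 fell and 0 rose, and 0 passed adjusted over the list alone in edgeR, with 21 at an unadjusted p under 0.05 (median −0.11, negative for 73; camera adjusted p = 1.11e-05; adjusted p = 0.949 with an estimated correlation). Cox6a2 and Cox5b, subunits of cytochrome c oxidase, fell to 0.711 and 0.879 (adjusted p = 0.0224 and 0.0377). Cox6a2 reached 0.0638 without AC-T 502, and Cox5b lost its call on omission of any 1 of 7 libraries, to at most 0.0909 without AC-T 602. Of 83 cytosolic ribosomal protein genes, 5 fell and 0 rose, also adjusted over the list alone (median −0.08, negative for 75; camera adjusted p = 0.000479; adjusted p = 0.974 with an estimated correlation). Rpl9 and Rpl10a fell to 0.809 and 0.844, and reads shared with ribosomal pseudogenes make these values uncertain. The ribosomal call ended without AC-T 602 (0.0539). Of 13 mitochondrially encoded protein genes, 0 passed in edgeR over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median −0.17; camera adjusted p = 0.0256; adjusted p = 0.974 with an estimated correlation). That list call ended without AC-T 600 (0.183), AC-T 602 (0.106), saline 301 (0.0902) or saline 302 (0.132). Against saline series 3, 9 mitochondrially encoded genes fell (median −0.33), and against saline series 2, 0 did in edgeR (median −0.09). Ribosomal genes lower against series 3 and series 2 numbered 13 and 3, and respiratory genes 10 and 17. Between AC-T series 6 and 5 the medians of the respiratory, ribosomal and mitochondrially encoded lists were −0.17, −0.19 and −0.36 (n = 2 and 3), each further from 0 than the change after AC-T, and 1, 0 and 0 genes passed in edgeR. Exact permutation p values of the respiratory, ribosomal and mitochondrially encoded scores were 0.0260, 0.225 and 0.156, in libraries with thalamic scores of 4.95 ± 0.336 and 6.07 ± 0.359.

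**Figure D3:**
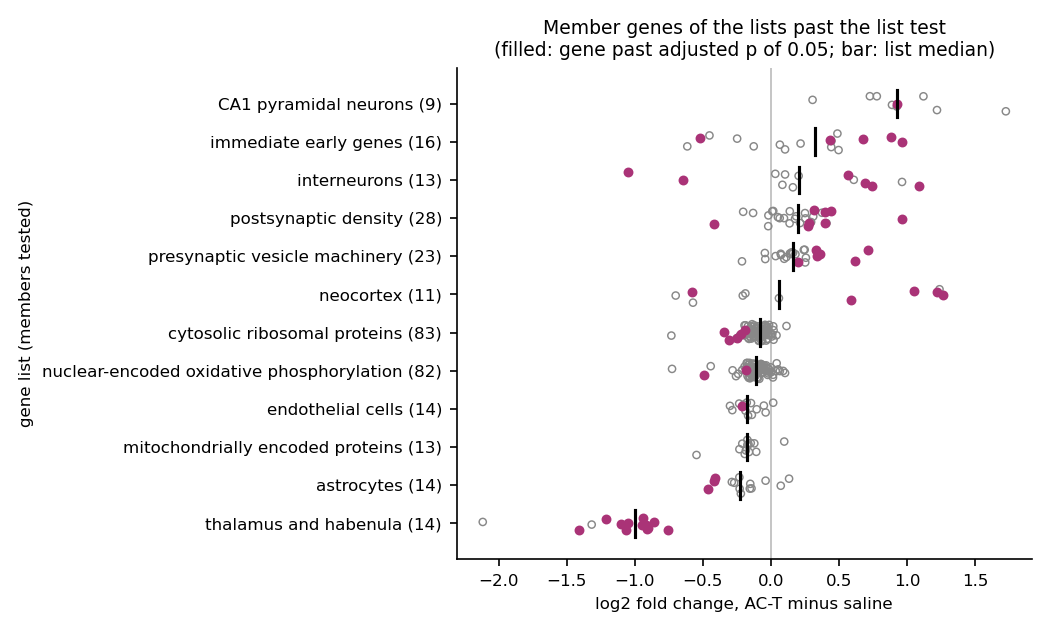
Log2 fold change, AC-T minus saline (horizontal axis), of the member genes of the 12 lists past camera (vertical axis, with the number of members tested); filled points are genes with an adjusted p under 0.05 and bars are list medians. Medians run from −1.002 for the thalamus and habenula to 0.93 for CA1 pyramidal neurons.

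Lists of inflammation, DNA damage, myelin and neurogenesis did not pass. Genes past the threshold numbered 0 of 15 for homeostatic microglia, 0 of 11 for cytokines and the NF-kB response, 0 of 21 for the interferon response, 0 of 7 for complement and 0 of 17 for reactive astrocytes in edgeR. At an unadjusted p under 0.05 the numbers were 0, 5, 0, 0 and 1. These lists were fixed at 15, 22, 24, 11 and 23 genes, and members not tested are not covered. Of 12 neurogenesis genes 1 fell, and of 20 tubulin and microtubule genes 2 rose. Of 14 activated microglia genes, 1 fell, Csf1 (adjusted p = 0.0250). Aif1, a microglial gene, had a log2 fold change of 0.02 ± 0.14 (SE; adjusted p = 0.946), and its sign changed with upper-quartile factors and with library totals. Of 20 p53 targets and DNA damage genes, 1 rose, the kinase gene Plk2 (1.59-fold; adjusted p = 0.0224), and the cell cycle inhibitor Cdkn1a stood at 0.19 ± 0.17 (adjusted p = 0.553). Csf1 lost its call without AC-T 502 (0.0638), AC-T 602 (0.0570) or saline 301 (0.0502), and Plk2 without AC-T 502 (0.0612), AC-T 600 (0.0509) or AC-T 602 (0.0551). Of 19 myelin genes 0 passed in edgeR and 0 had an unadjusted p under 0.05, with Mbp, the myelin basic protein gene, at −0.16 ± 0.14 (adjusted p = 0.532). Dcx, a marker of immature neurons, stood at 0.14 ± 0.08 (adjusted p = 0.335), and the neurotrophin gene Bdnf at 0.10 ± 0.10 (adjusted p = 0.600). Ttr, the transthyretin gene of the choroid plexus, stood at 0.28 ± 1.25 (adjusted p = 0.925), and the haemoglobin gene Hba-a1 at −0.79 ± 0.36 (adjusted p = 0.202).

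To ask whether mice of a treatment differed by mouse number, the series were compared within each treatment. In saline, series 3 differed from series 2 in 158 genes, 81 higher and 77 lower (n = 3 and 3). The thalamic median of that comparison was −0.46, with 0 of 14 genes past the threshold in edgeR. In AC-T, series 6 differed from series 5 in 18 genes, 12 higher and 6 lower (n = 2 and 3), and limma-voom gave 0 genes, with 2158 at an unadjusted p under 0.05. AC-T differed from saline series 3 in 1113 genes, with 9 thalamic markers lower (median −0.73). Against saline series 2 the numbers were 1753 genes and 14 thalamic markers lower (median −1.21). No series holds both treatments, and with series as a random effect 293 genes passed.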

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

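No test was added for these values after they were seen. In each of 214 groups of 5 or 6 libraries, the gap between the highest or lowest library and its neighbour was compared with the range of the group. A lone library stood apart in 9 groups, where chance gives about 1 in 20. AC-T 503 was the lone library in 3 of the 9.

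Nxph3 was 34.99 CPM in AC-T 503 and 28.2 to 29.3 CPM in the other 4 AC-T libraries. Cplx3 was 29.6 CPM in AC-T 503 against 20.3 to 22.5. Plk2 was lowest there, at 114 CPM against 147 to 154. Nov reached 118 CPM in AC-T 502 against 65.0 to 77.7. The mitochondrial gene mt-Nd3 was lowest in AC-T 600, at 398 CPM against 515 to 552. Zbtb16, a zinc finger transcription factor induced by glucocorticoids, was 61.2 CPM in AC-T 602 against 33.6 to 39.2. Among saline libraries, Shox2 was 47.2 CPM in saline 201 against 27.2 to 34.3, and Pecam1 was 32.5 CPM in saline 203 against 28.0 to 29.7. Vamp2, a vesicle SNARE gene, was lowest in saline 300, at 820.4 CPM against 903 to 938.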

How the results depend on the processing

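The fits of genes with a value above 0 in all libraries, and with the thalamic list score as covariate, were chosen only after the result was seen. Of 78 named genes that passed, 49 passed in each fit that left out 1 library and tested the gene, and 29 lost the call in some. Zfhx3, counted among the 49, was tested in only 6 of the 11 such fits. With series as a random effect 33 of the 78 kept the call, with the dissection component 17, with the thalamic score 1, and with DESeq2 78. Of 12 lists, 8 kept their call in each fit that left out 1 library, and 7 lists kept it with the thalamic score. No gene called in an alternative and in the fit reported changed direction.

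The 1301 genes became 625 (without AC-T 502) to 1229 (without saline 302) when 1 library was left out, with 348 to 745 higher and 277 to 544 lower. Beyond 1.5 times were also AC-T 602 (681 genes, 372 higher, 309 lower), saline 202 (815, with 481 and 334), saline 300 (832, with 426 higher) and saline 203 (343 lower). Leaving out series lowered the number of libraries: 549 genes (395 higher, 154 lower) without saline series 2, 317 (112 and 205) without AC-T series 5 and 409 (215 and 194) without AC-T series 6. Library totals gave 487 higher. The dissection component gave 178 (124 and 54), the thalamic score 1 (1 and 0), DESeq2 2512 (1341 and 1171) and series as a random effect 293 (169 and 124). By construction, adjusted p under 0.10 gave 2295 (1347 and 948) and a test against 1.2-fold gave 86 (48 and 38). Genes above 0 in all libraries gave 1442, of which 1239 were among the 1301. For the AC-T series, limma-voom gave 0 genes, with 2158 at an unadjusted p under 0.05.

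Of the lists, 0 passed with an estimated correlation (0 higher, 0 lower; 3 at an unadjusted p under 0.05) and 3 with fry (1 higher, 2 lower). The dissection component gave 19, with 10 lower. Without saline series 3 there were 6 (3 higher, 3 lower), without AC-T series 5 10 were lower, and without AC-T series 6 3 were lower.

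Signs reversed as follows. With the thalamic score, CA1 became −0.13, Gpr161 −0.080, Man1a −0.14, Pcp4 0.027 and Ttr −3.15. The neocortex median was −0.028 (without AC-T 502) to 0.16 with 1 library left out and −0.10 without saline series 3. Gfap was −0.11 to 0.012 with 1 library left out, 0.15 without saline series 3 and 0.052 without AC-T series 6. Aif1 was −0.063 to 0.11 with 1 library left out, −0.0015 with upper-quartile factors, −0.00011 with library totals, −0.039 without saline series 2, −0.24 without AC-T series 5, −0.0065 with voom, −0.018 with quality weights and −0.023 with series as a random effect. Ttr was −0.47 to 1.12 with 1 library left out, −2.58 with the dissection component, −0.46 without saline series 2 and −0.92 without AC-T series 6. Without saline series 3, Cdkn1a was −0.12 and Mbp 0.041. The cause was not tested, except where the number of libraries or the threshold is itself the change.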

Other observations

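Tests chosen only after the result was seen were those without saline series 2, both tests of Xist, the estimated correlation as an account of the respiratory list, the fit with the thalamic score, and the values with the longest transcript. The patterns weighed were themselves noticed in these data.

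Genes of inhibitory and excitatory transmission changed in both directions. Slc6a11, the GABA transporter of astrocytes, fell to 0.510 of its saline level (233 ± 32.7 against 456 ± 49.8 CPM; SD, n = 5 and 6; adjusted p = 0.000665), and Gabrd, the delta subunit of GABA-A receptors, fell to 0.703. Of 19 GABA signalling genes, 2 rose and 3 fell, with 4 and 3 adjusted over the list alone. Of 24 glutamate receptor genes, 2 rose and 4 fell, with 4 and 6 adjusted over the list alone; Grin2d, an NMDA receptor subunit, fell to 0.615. Of 31 potassium channel genes, 3 rose and 3 fell, with Kcnh2 at 0.675 and Kcnf1 at 1.36-fold. Of 23 sodium and calcium channel genes, 2 rose and 2 fell, with Cacnb1 at 1.33-fold and Cacna1g, a T-type calcium channel, at 0.623. Of 5 CA2 markers 2 fell, Cacng5 to 0.583 and Pcp4 to 0.561, and adjusted over the list alone 1 rose and 2 fell. Pcp4 lost its call without AC-T 502 (0.0605) or AC-T 602 (0.0524). The CA2 list had a camera adjusted p of 0.0591 and a fry adjusted p of 0.0158. None of the other lists in this paragraph passed camera. These genes were measured beside thalamic scores of 4.95 ± 0.336 after AC-T and 6.07 ± 0.359 after saline. With that score as covariate, log2 fold changes went from −0.97 to −0.67 for Slc6a11, from −0.51 to −0.15 for Gabrd, from −0.70 to −0.089 for Grin2d and from −0.68 to −0.039 for Cacna1g, and all 4 lost the call. Both CA2 genes also lost the call with it, and Pcp4 went from −0.83 to 0.027. Cacng5 was −0.26 in the alternative fit nearest 0.

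Of 11 glucocorticoid response genes, Zbtb16 rose 1.85-fold (41.9 ± 11.04 against 22.7 ± 2.64 CPM; adjusted p = 0.00595) and 1 fell, Ddit4. Of 10 heat shock genes, 2 rose, Hspa1b 1.46-fold and Hsph1 1.21-fold, and the list had a camera adjusted p of 0.0571. Of 16 circadian genes 1 rose and 2 fell, with Per3 at 0.847. Among markers of other tissue that the punch could hold, 12 of 14 thalamic and 5 of 11 neocortical genes passed, as given above. In edgeR 0 passed of 14 for the choroid plexus, of 9 for ependymal cells, of 10 for meningeal fibroblasts and of 9 for the striatum. In each of these 4 lists 0 had an unadjusted p under 0.05. Other tissue still varied between punches: choroid plexus scores ran from −1.62 to 5.99 in saline and from −0.84 to 5.83 in AC-T libraries, and against saline series 2 alone 4 striatal markers rose (median 0.71) and 2 meningeal markers fell (median −0.59). Subfield markers gave 0 of 9 for CA3 and 0 of 10 for dentate granule neurons, with 1 and 2 at an unadjusted p under 0.05. Of 5 blood cell genes 0 passed and 2 had an unadjusted p under 0.05. Ddit4 and Hsph1 each lost the call on omission of any 1 of 8 libraries, to at most 0.0851 without AC-T 600 and 0.0929 without AC-T 602.

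Lower thalamic markers with higher CA1 and neocortical genes formed the first pattern, within 1301 genes that chance splits of the libraries did not match: 1 of 100 splits, the real one, gave as many, and the highest other gave 90. These splits exchanged single mice and not whole series, so they cannot set aside a chance difference between series. Saline series 3 and 2 differed in 158 genes. The idea that saline series 2 alone made the pattern was excluded for the thalamic markers, whose median was −0.73 without it (median SE 0.19). For the CA1 markers the median was 0.93 with series 2 and 0.40 without it (median SE 0.28 and 0.13). Between saline series 3 and 2 the CA1 median was also 0.93, so the size of the rise depended on series 2. The value of 0.40 lay between the bounds set for and against series 2 alone, so it and AC-T cannot be told apart. Of the 4 neocortical genes called higher, 3 stayed past the threshold in edgeR without series 2, which argues against series 2 alone for those 3. Fezf2 did not (0.77, adjusted p = 0.0681) and stays open. The neocortical median was 0.23 without series 2 (median SE 0.15) and 0.06 with it. A candidate explanation for the thalamic and CA1 genes is that AC-T punches held less thalamic tissue: across 1289 called genes outside the list, slopes on the thalamic score within groups predicted the fold changes with Spearman rho 0.62 (0.49 in saline and 0.51 in AC-T libraries alone), above 97.0% of 99 permutations within groups (highest 0.79), 68.8% of these genes and 4 of the 6 called CA1 and neocortical genes had the predicted sign, and with the score fitted CA1 went from 0.93 to −0.13. In saline the thalamic score also separated the series, at 6.28 to 6.55 in series 2 and 5.64 to 5.82 in series 3. Slopes in saline can therefore reflect series as well as tissue. The medians of the neocortical and interneuron lists did not shrink with the score fitted, and went from 0.06 to 0.45 and from 0.20 to 0.46 (median SE 0.31 and 0.26). Fitting the score left 1 gene, Bmp3, which is listed at 0 in all saline libraries, as the median absolute log2 fold change of called genes went from 0.32 to 0.23 and the median SE from 0.07 to 0.14; no thalamic score overlapped between treatments, so an effect of AC-T on these cells stays open and untested.

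Xist at 0 in saline 300 formed the second pattern. The limit under which the table lists 0 was excluded as its source: the lowest Xist value of the other libraries was 10.1 times the level under which 99% of lowest listed values fell (12.8 times with the longest transcript per gene). Ddx3x, Eif2s3x, Kdm5c and Kdm6a, which escape X inactivation, were each lowest of the 11 libraries in saline 300, with a mean log2 ratio to the other saline libraries of −0.41 (the others ran from −0.06 to 0.04). This mouse may therefore lack an inactive X chromosome, as a male does, and a wrong label or an exchanged sample stays open. Genes of the Y chromosome were not examined for this question. Without saline 300, 832 genes passed.

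Lower respiratory and ribosomal lists, whose transcripts are short, formed the third pattern. Removal of a smooth trend with transcript length moved the respiratory median from −0.11 to −0.077 (−0.069 with the longest transcript), between the bounds set for and against that trend as the cause, so the trend and a change of these genes cannot be told apart. Spread shared by all members is a candidate explanation, as the unadjusted p was 0.275 with an estimated correlation (camera, limma). For the number of lists, chance cannot be excluded: 75 of 100 splits gave at least the 12 lists of the real split, and the highest other gave 25. An effect of AC-T on these genes stays open and untested.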
